A study of Mus musculus with 6 samples.

How the data were processed

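RNA was measured on Agilent whole-genome mouse arrays read in 2 colours. The mice, per the labels, were on the C57BL/6J background and carried a floxed Ror1 gene, a tamoxifen-inducible Cre recombinase driven by the CAG promoter, and a human EGFR transgene with an activating deletion driven by the surfactant protein C promoter, which is active in alveolar epithelium and gives lung tumors. They received tamoxifen or corn oil for 4 weeks, from 16 to 20 weeks of age, and tumor RNA was taken at 20 weeks. Per the labels, total RNA was isolated with a column kit and 50 ng were labelled with Cy3 or Cy5. There were 3 tamoxifen and 3 oil samples. Each tamoxifen sample shared its arrays with the oil sample of the same number, and each such couple was hybridised 2 times with the dyes exchanged, giving 6 arrays on 1 slide in 1 scan. No batch within the series was therefore tested.

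The deposited scanner files hold the intensity of each spot, as a mean foreground and a median local background in each channel, with no normalization, per the file headers. The scanner software was Agilent Feature Extraction 12.0.3.1, per the submitters' processing notes. The same deposited files hold a log10 ratio of Cy5 over Cy3 that the software made after background subtraction, spatial detrending and linear and lowess dye normalization, per the file headers. They also hold, per the file headers, flags of 0 or 1 for spots well above background, saturated or outlying. The deposited table of the whole series holds log2 ratios of Cy5 over Cy3. Its scale and direction were settled by setting each column against the log10 ratio of the same array, where the slope was 3.32 over 27624 probes for every array. Its column medians were 0.14, -0.14 and -0.06 on the arrays of couples 1, 2 and 3 with tamoxifen in Cy5, and 0.13, -0.15 and -0.01 with oil in Cy5. No centring was added to the scanner software's own dye normalization, so none of scale, centring and direction stayed unknown. What the submitters tested, and with which statistical tool, is not given in the sources used here. Probe positions in the files are on mouse build mm9. No sequence or exon annotation of that build was used here, so probes are given by position and not by exon, intron or UTR.

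From the intensities, the background was corrected in limma 3.58.1 under R 4.3.3 by normexp with an offset of 50 on all 62976 spots of an array. Loess normalization followed within each array, with the 3671 control spots at weight 0 and then removed, and spots with an outlier flag were left out. Between 89 and 132 spots per array had such a flag, and 0 were saturated. Spots of a probe were averaged, giving 56605 probes under 36870 gene names. The probe with the highest mean log2 signal stood for a gene name. It was tested if it was well above background on both arrays of at least 2 couples, in the channel of tamoxifen or in that of oil. This left 20475 genes, after 2 were dropped for a missing spot. Accessions on the array were matched without versions to a reference gene table of assembly GRCm38.p6 for current symbols. Of the 36870 gene names 23464 matched, among them 14334 of those tested, and the others kept the name in the files. Each array was turned to tamoxifen over oil, and the 2 arrays of a couple were averaged, which cancels a dye effect and leaves 3 replicates. Technical dye swaps were not counted as replicates. The log2 ratios were tested against 0, two-sided, with limma (lmFit and eBayes) and Benjamini-Hochberg adjustment, with 0.05 as the threshold. Errors given with a log2 ratio are the SD over the 3 couples unless SE is written. The number of arrays limits the precision: the median SE of a gene was 0.098 on the log2 scale. A ratio on this scale is pulled toward 0 for dim probes, as the offset is added to both channels.

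A probe not well above background on every array of a group has only a bound there. It is given as "at least N-fold", the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. These are means of normalized log2 values per channel, after loess and Aquantile normalization, with the arrays of a sample averaged first.

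A total of 30 gene lists, the rule for named genes, the tests and the alternatives were written down before the data were examined. The lists covered HIF-1 targets, glycolysis, ROR and Wnt5a receptors and ligands, caveolae, the EGFR-MAPK response, proliferation, p53 targets, the unfolded protein response, sterol synthesis, xenobiotic metabolism, the interferon response, inflammatory cytokines, immediate early and heat shock genes and EMT. The others held markers of alveolar type 2, alveolar type 1, club, ciliated, mesothelial, endothelial, smooth muscle, heart muscle, erythroid and fat cells, of alveolar macrophages, monocytes and dendritic cells, neutrophils, T and NK cells, B and plasma cells, and of fibroblasts and matrix. They had 480 members in all, of which 479 were on the array and 429 were tested. Each list was tested with limma's camera with a preset correlation of 0.01, adjusted over the 30 lists, beside camera with an estimated correlation and fry. Camera compares a list with all other genes. Fry's directional p tests whether a list's genes move, on balance, one way, its mixed p whether they change in either direction, and neither compares the list with other genes.

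Ror1, Ror2, Hif1a, Egfr and Nkx2-1 were always named. Otherwise the rule named, per direction, the 10 genes with the largest change among those that passed the test with the same direction on all 6 arrays and had a proper gene symbol. Places left open were filled by the smallest unadjusted p among genes with the same direction on all 6 arrays and a ratio of at least 1.5-fold, given as values that did not pass. From each list it named the 4 members with the smallest p, or 2 where the list did not pass, of which 1 gene is not reported here. Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were read as a check of the sex of the mice.

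The averaging of couples and the tests were tried on simulated log2 ratios of tamoxifen over oil. Each of 20 simulations had 20475 genes, 200 of them changed, and left out the processing of the intensities. At the adjusted threshold 0.75% of genes changed by 1.5-fold were recovered, 44.6% at 2-fold and 82.5% at 4-fold, and the unadjusted p was under 0.05 for 90.7%, 97.3% and 99.8% of them. Over all simulations 51 calls were false and 1697 true. A list shifted by 0.3 on the log2 scale was found in 20 of 20 simulations, with 4 other lists called over all of them. The simulated genes were drawn independently of each other, while real lists had estimated correlations of up to 0.92 (proliferation). These counts therefore do not give the power or error rate of camera in the real data. When the tamoxifen channel of 200 genes was doubled in the intensities, 200 were read as higher, with a median log2 ratio of 0.97 for the brighter genes and 0.66 for the dimmer ones.

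The alternatives were no background correction, an offset of 16, the scanner software's log ratio, the series table, median centring in place of loess, no filter on dim probes or a stricter one, outlier spots kept, the mean of a gene's probes, every probe on its own, an intensity trend in eBayes, array weights, a single dye orientation, the 6 arrays with the couple as a random block or as if independent, each couple left out, the channels taken apart with and without the number as a block, an adjusted threshold of 0.1, and camera with an estimated correlation.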

Results

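Gene expression was compared in lung tumors of mice that carry a mutant human EGFR transgene and a floxed Ror1 gene. Per the labels, tamoxifen, meant to switch on Cre recombinase, was given for 3 samples and corn oil for the other 3. Ror1 is a receptor tyrosine kinase-like membrane protein that binds Wnt5a. The series title asks what loss of Ror1 does in lung adenocarcinoma and points to a regulator of HIF-1α, the oxygen-sensitive transcription factor. Each tamoxifen sample was hybridised with the oil sample of the same number on 2 arrays with the dyes exchanged, so the data are 6 arrays in 3 couples. Between 51.8% and 58.8% of probes were well above background per array and channel. The ratios of the 2 dye orientations of a couple correlated across genes with r of 0.76, 0.77 and 0.79 in couples 1, 2 and 3. Between couples, the ratios correlated with r of 0.17 (couples 1 and 2), 0.12 (1 and 3) and -0.02 (2 and 3), where genes are not independent replicates. The labels do not say whether the numbered samples are separate animals, so limma's p-values for genes measure only the spread between these samples. Camera's p-values with the preset correlation set a list against other genes. They do not measure the spread of a list's mean between couples.

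The first question was whether Ror1 was lost in the samples labelled tamoxifen. The Ror1 probe, on chromosome 4 from 100115077 to 100115136 (mm9, accession NM_013845, sequence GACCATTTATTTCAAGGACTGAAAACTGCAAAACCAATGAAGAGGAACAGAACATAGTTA), was well above background in all 6 tamoxifen and all 6 oil readings. Its log2 ratio of tamoxifen over oil was 0.47, 0.42 and 0.06 on the arrays of couples 1, 2 and 3 with tamoxifen in Cy5, and 0.70, 0.47 and 0.29 with tamoxifen in Cy3. The couples averaged 0.58, 0.44 and 0.18, with a mean of 0.40 ± 0.21 (SD, n = 3 couples), a ratio of 1.32-fold toward the samples labelled tamoxifen (limma, p adjusted over all genes = 0.69). This goes against the direction that the treatment label gives for a deleted gene, and it did not pass the test. The labels do not say which exon is floxed, and a probe outside the deleted part checks nothing, so neither the deletion nor the labels could be checked by this probe. Another Ror1 probe, on chromosome 4 from 100008142 to 100008201 (mm9, NM_001312690), was not well above background in any reading. Directions given from here on are therefore those of samples labelled tamoxifen against samples labelled oil.

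Hif1a, which encodes the HIF-1α protein itself, had a log2 ratio of -0.16 ± 0.34 (SD, n = 3 couples), with -0.33, 0.23 and -0.37 in couples 1, 2 and 3 (limma, adjusted p = 0.82). A dimmer Hif1a probe gave the same mean of -0.16 from other couple values, -0.75, 0.22 and 0.04. Ror2, the paralog of Ror1 (well above background in 4 of 6 tamoxifen readings), was at -0.13 ± 0.26, mouse Egfr at -0.15 ± 0.14, and Nkx2-1, the lineage transcription factor of lung epithelium, at -0.03 ± 0.18 (adjusted p = 0.83, 0.74 and 0.96). Nkx2-1 moved to the other side of 0, at 0.03, with median centring, and Ror2 did so, at 0.02, without couple 2. The human transgene was not analysed here.

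The lowest ratio among the named genes was that of Cox6a2, a subunit of cytochrome c oxidase known from heart and skeletal muscle, at -1.86 ± 0.21 (SD, n = 3 couples), 3.63-fold dimmer in the samples labelled tamoxifen (chromosome 7 from 135349160 to 135349219, mm9). Its couples were at -1.65, -1.87 and -2.07, yet its adjusted p was 0.41 in limma. Gjb6, a connexin of gap junctions, was at -1.55 ± 0.33, Col6a1, a chain of collagen VI, at -1.36 ± 0.27, Rprm, a cell cycle inhibitor induced by p53, at -1.11 ± 0.18, and Rasd2, a small GTPase, at -0.997 ± 0.14. Per1, a repressor in the circadian clock, was at -0.91 ± 0.16, Hdac9, a histone deacetylase, at -0.76 ± 0.10, Sult2b1, which sulfates cholesterol, at -0.74 ± 0.04, Lpin2, a phosphatidate phosphatase, at -0.68 ± 0.08, and Lox, which crosslinks collagen and elastin, at -0.63 ± 0.03. On the higher side, Rec8, a cohesin subunit of meiosis, was at 1.35 ± 0.28 and Prxl2a, a peroxiredoxin-like protein, at 0.87 ± 0.06 (chromosome 14 from 56244160 to 56244219 and from 41807029 to 41807088). Dglucy, a D-glutamate cyclase, was at 0.86 ± 0.25, Itpripl1 at 0.85 ± 0.14, H2-Eb2, an MHC class II chain, at 0.84 ± 0.27, Bpifb5 at 0.79 ± 0.24, Arxes1 at 0.75 ± 0.10, Srd5a1, a steroid reductase, at 0.68 ± 0.10, Ccng1, a cyclin induced by p53, at 0.65 ± 0.13, and Xylb, a xylulokinase, at 0.60 ± 0.12. Within each direction, these 20 genes had the smallest unadjusted p among those of the same sign on all 6 arrays and at least 1.5-fold. They are not the 20 with the smallest p over both directions together, as some lower genes left out had a smaller p than some higher genes. None of these 20 genes passed, with adjusted p from 0.41 to 0.67.

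Of 20475 genes, 0 passed limma at an adjusted p under 0.05, and the lowest adjusted p was 0.41. At an unadjusted p under 0.05 there were 1435 genes, 614 higher and 821 lower, where chance gives 1024. All 3 couples had the same sign for 6189 genes (30.2%, against 25% by chance), and all 6 arrays for 2712, of which 71 higher and 130 lower genes differed by at least 1.5-fold. A fit of the 6 arrays with the couple as a random block called 9 genes (3 higher, 6 lower), among them Cox6a2 (adjusted p = 0.0014), Rec8, Col6a1 and Gjb6 (each 0.014), Rasd2 (0.017), Prxl2a (0.031), and Itpripl1 and Per1 (each 0.038). The channels taken apart as 3 against 3 samples gave 1 gene, Cox6a2 (limma, adjusted p = 0.0088, with 0.0014 to 0.97 over its alternatives), and the 6 arrays as if independent, which counts each sample pair 2 times, gave 179. Within couples, 129 genes were over 2-fold higher and 186 over 2-fold lower in couple 1, 104 and 139 in couple 2, and 111 and 162 in couple 3.

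**Figure D1:**
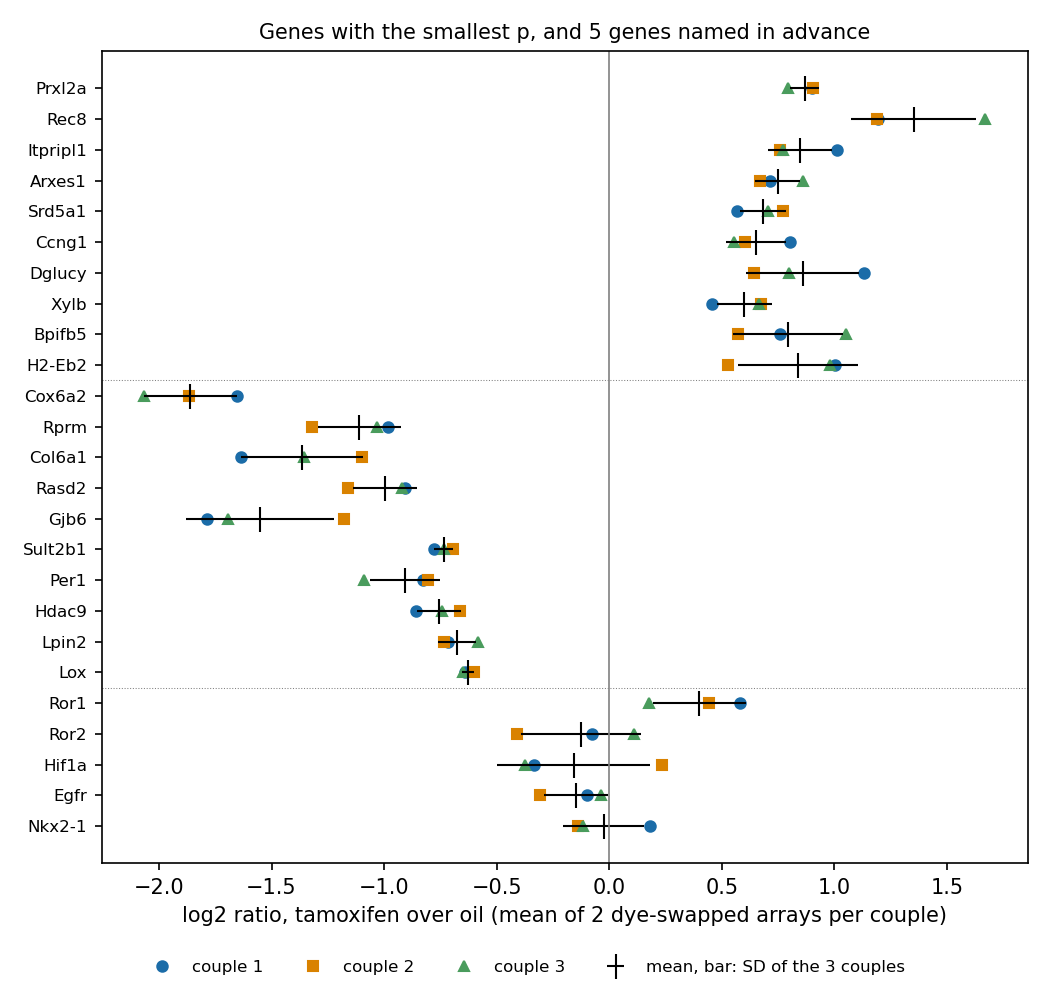
Log2 ratio of tamoxifen over oil (x axis) of Ror1 and the other genes named by rule, with a point per couple (mean of 2 dye-swapped arrays), a tick at the mean and a bar of 1 SD over the 3 couples. The points of Cox6a2 lie from -2.07 to -1.65 and those of Ror1 from 0.18 to 0.58, and no gene shown passed the adjusted test.

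Of 30 gene lists, 8 passed camera with the preset correlation, 2 higher and 6 lower in the samples labelled tamoxifen. With an estimated correlation 0 passed, and every adjusted p was at least 0.84. The lowest unadjusted p of that form of camera was 0.056, for immediate early and heat shock genes. It rests on the few degrees of freedom that 3 couples leave, which puts an adjusted pass nearly out of reach. Its result therefore neither upholds nor overturns the 8 calls, which stay unsettled. The preset of 0.01 was far below the estimated correlations of the proliferation (0.92), alveolar macrophage (0.83), HIF-1 (0.43) and p53 (0.32) lists. For the immediate early, type 2, fibroblast and heart muscle lists these were 0.04, 0.03, 0.09 and -0.065. Turning the sign of couple 1, 2 or 3 left 7, 7 and 11 lists past, so the count of 8 does not set the labelled split apart. By fry 0 lists passed in 1 direction and 2 passed the mixed test, genes of the epithelial-mesenchymal transition (EMT; adjusted p = 0.034) and alveolar type 2 markers (0.040). No member of any list passed over all genes. Counts given below as "adjusted over the list alone" treat each list as its own family of tests.

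HIF-1 targets, genes that the factor induces under low oxygen, were lower: 25 of 30 members had a ratio below 0, and the list mean was -0.30 ± 0.42 (SD, n = 3 couples; camera, adjusted p = 6.9e-05). The adjusted p = 0.84 with an estimated correlation. Nearly all of the shift lay in couple 1, with means of -0.79, -0.02 and -0.09 in couples 1, 2 and 3, and of -0.73 and -0.86 on the 2 dye-swapped arrays of couple 1. Without couple 1 the mean was -0.06 and the adjusted p = 0.72 (camera; 5.7e-08 to 0.84 over all alternatives). Lox was at -0.63 ± 0.03, Tfrc, the transferrin receptor, at -0.47 ± 0.13, Egln1, an oxygen-sensing prolyl hydroxylase, at -0.51 ± 0.19, and Bnip3, a mitophagy receptor, at -0.98 ± 0.50. Of the 30, 4 members passed when adjusted over the list alone, 8 had an unadjusted p under 0.05, and 10 were lower in all 3 couples. Vegfa, the angiogenic growth factor, was at -0.13 ± 0.33 and Pfkfb4, a regulator of glycolysis, at 0.23 ± 0.09. Glycolysis genes, 4 of which are also in the HIF-1 list, had a mean of -0.16 ± 0.38 with couple means of -0.57, 0.20 and -0.12 and did not pass (14 of 17 below 0; camera, adjusted p = 0.055; 0 adjusted over the list alone). Hexokinase Hk2 was at -0.59 ± 0.46 and Aldoa, an aldolase, at -0.48 ± 0.41. The glycolysis mean was 0.04 without couple 1, and without couple 2 it was -0.34 (camera, adjusted p = 2.6e-05), and the list passed in 7 of 21 alternatives. Alveolar macrophage markers were at -1.10, 0.55 and -0.42 in couples 1, 2 and 3, with the same signs as glycolysis genes, while HIF-1 targets stayed near 0 in couple 2. Couple 1 also differed in sex-linked signal, as given with the sex check.

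**Figure D2:**
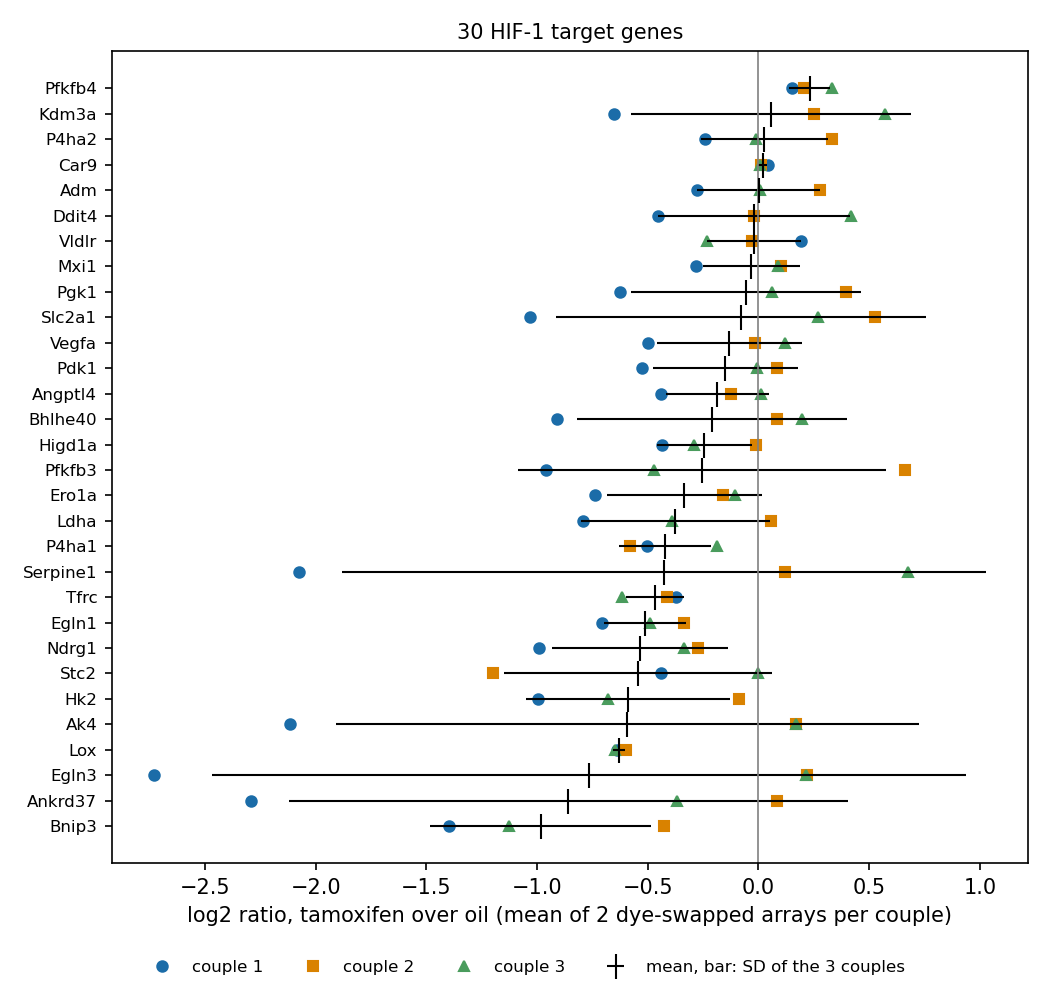
Log2 ratio of tamoxifen over oil (x axis) of the 30 HIF-1 target genes, with a point per couple (mean of 2 dye-swapped arrays), a tick at the mean and a bar of 1 SD over the 3 couples. Couple 1 is the lowest for most genes, with a list mean of -0.79, against -0.02 and -0.09 in couples 2 and 3.

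Immediate early and heat shock genes, which respond within minutes to growth factors and stress, were lower in each couple, at -0.32, -0.38 and -0.22, with a mean of -0.31 ± 0.08 (SD, n = 3 couples) and 14 of 15 members below 0 (camera, adjusted p = 5.6e-05). The adjusted p = 0.84 with an estimated correlation. Fos, a subunit of the AP-1 transcription factor, was at -0.55 ± 0.13, Zfp36, which destabilises cytokine mRNAs, at -0.41 ± 0.01, and the chaperones Hspa1b and Hspa1a at -1.02 ± 0.63 and -0.73 ± 0.44. Adjusted over the list alone, 4 members passed.

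Alveolar type 2 markers, genes of the surfactant-making cells in which the EGFR transgene is driven, were lower at -0.19, -0.18 and -0.33 in couples 1, 2 and 3 (mean -0.23 ± 0.09, SD, n = 3 couples; 13 of 16 below 0; camera, adjusted p = 0.0022). The adjusted p = 0.84 with an estimated correlation, and 1 member passed adjusted over the list alone. The surfactant protein genes Sftpb, Sftpd and Sftpa1 were at -0.62 ± 0.09, -0.37 ± 0.22 and -0.30 ± 0.09, while Il33, a cytokine, was at 0.54 ± 0.23. Without couple 3 the list mean was -0.18 (camera, adjusted p = 0.051). Markers of alveolar type 1 cells, the flat gas-exchange cells, had means of -0.34, -0.13 and 0.47 in couples 1, 2 and 3, with a mean of 0.00, a median of 0.05 and a camera direction of lower (adjusted p = 0.97). Their water channel Aqp5 was at -0.84 ± 0.29, the 1 member that passed adjusted over the list alone, and Gprc5a at -0.27 ± 0.20. The type 1 list was at -0.23 without couple 3 (adjusted p = 0.018). Club cell markers averaged -0.18 ± 0.34 (adjusted p = 0.71; Cckar 0.61 ± 0.48, Cbr2 -1.05 ± 1.35) and ciliated cell markers -0.12 ± 0.28 (0.095; Tekt1 -0.21 ± 0.15, Mcidas -0.18 ± 0.10), with 0 members past adjusted over the list alone. The ciliated mean was -0.26 without couple 3 (adjusted p = 0.018) and 0.01 without couple 2, and the list passed in 2 of 21 alternatives. The type 2 list passed in 18 of 21.

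Fibroblast and matrix genes were lower in each couple, at -0.22, -0.23 and -0.13 (mean -0.20 ± 0.05, SD, n = 3 couples; 14 of 16 below 0; camera, adjusted p = 0.0055). The adjusted p = 0.84 with an estimated correlation. Col6a1 passed adjusted over the list alone, and Eln, which encodes elastin, was at -0.55 ± 0.45, with the collagen I genes Col1a2 at -0.32 ± 0.24 and Col1a1 at -0.22 ± 0.14. Heart muscle markers, genes of a tissue outside the tumor, had 8 of 8 tested members below 0 and a mean of -0.22 ± 0.21 (-0.15, -0.46 and -0.06 in couples 1, 2 and 3; camera, adjusted p = 0.042). The adjusted p = 0.84 with an estimated correlation, and 0 passed adjusted over the list alone. Among them, the atrial myosin light chain Myl7 was at -0.46 ± 0.25, Tnni3 at -0.24 ± 0.24, Tnnt2 at -0.16 ± 0.11 and Nppa at -0.11 ± 0.14. Myl7 was well above background in 3 of 6 tamoxifen and 6 of 6 oil readings and Tnni3 in 3 of 6 and 5 of 6, so their ratios are only rough. Myh6, singled out after its values were seen, was at -2.54 in couple 2 and at -0.16 and 0.52 in couples 1 and 3, and so carries much of the couple 2 mean. The heart muscle call was lost without any of the couples: the means were -0.26 without couple 1, -0.11 without couple 2 and -0.31 without couple 3 (camera, adjusted p = 0.068, 0.21 and 0.051). Smooth muscle markers averaged -0.06 ± 0.07 (adjusted p = 0.33; Actg2 -0.15 ± 0.15, Myh11 -0.12 ± 0.07), mesothelial markers -0.27 ± 0.21 over 4 tested members (0.055; Upk1b -0.28 ± 0.17, Wt1 -0.14 ± 0.06, well above background in 4 of 6 tamoxifen readings), EMT genes -0.06 ± 0.15 (0.62; Mmp2 -0.47 ± 0.19, Fn1 -0.35 ± 0.31) and adipocyte markers -0.04 ± 0.08 (0.74; Cidec -0.16 ± 0.34, Retn -0.09 ± 0.09), with 0 members past adjusted over the list alone. Without couple 2 the mesothelial mean was -0.38 (adjusted p = 0.025), and the list passed in 8 of 21 alternatives. The heart muscle list passed in 13 of 21 and the fibroblast list in 19 of 21.

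Proliferation genes were higher by camera, with 32 of 34 members above 0 and a mean of 0.22 ± 0.64 (SD, n = 3 couples; adjusted p = 3.7e-04). The adjusted p = 0.88 with an estimated correlation. The couples went apart, at -0.36, 0.11 and 0.90 in couples 1, 2 and 3, and without couple 3 the mean was -0.12 (camera, adjusted p = 0.092). The replication helicase subunit Mcm2 was at 0.29 ± 0.24, the licensing factor Cdc6 at 0.24 ± 0.18, and Rrm2 and Tyms, which make nucleotides for DNA, at 0.63 ± 0.72 and 0.32 ± 0.37, with 0 members past adjusted over the list alone. Targets of p53, the DNA damage-responsive tumor suppressor, were higher by camera at 0.19 ± 0.21 (0.41, -0.01 and 0.17 in couples 1, 2 and 3; 12 of 16 above 0; adjusted p = 0.0074). The adjusted p = 0.84 with an estimated correlation. The 5 members that passed adjusted over the list alone were Ccng1 (0.65 ± 0.13), Trp53inp1 (0.37 ± 0.09), Phlda3 (0.43 ± 0.16), the death receptor gene Fas (0.33 ± 0.01) and, on the other side, Perp (-0.50 ± 0.24). Without couple 1 the p53 mean was 0.08 (camera, adjusted p = 0.14), and the list passed in 18 of 21 alternatives, as the proliferation list did in 19 of 21.

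Alveolar macrophage markers were lower by camera, with 14 of 16 members below 0 and a mean of -0.32 ± 0.83 (SD, n = 3 couples; adjusted p = 0.025), but couples 1, 2 and 3 were at -1.10, 0.55 and -0.42. The adjusted p = 0.88 with an estimated correlation, and 0 members passed adjusted over the list alone. Ctsk, a cathepsin, was at -0.52 ± 0.57, the fatty acid binding protein gene Fabp5 at -0.63 ± 0.79, Car4, a carbonic anhydrase, at -0.37 ± 0.46, and the scavenger receptor gene Msr1 at -0.22 ± 0.20. The macrophage mean was 0.07 without couple 1, -0.76 without couple 2 and -0.27 without couple 3 (camera, adjusted p = 0.39, 4.8e-09 and 0.057). The other blood and vessel lists did not pass: T and NK cell markers averaged 0.08 ± 0.02 (adjusted p = 0.055; Cd3d 0.21 ± 0.13, Lck 0.19 ± 0.11), B and plasma cell markers 0.08 ± 0.12 (0.12; Mzb1 0.16 ± 0.01, Ms4a1 0.15 ± 0.05), endothelial markers 0.05 ± 0.20 (0.24; Erg 0.22 ± 0.12, Cldn5 0.32 ± 0.52) and erythroid markers -0.17 ± 1.04 (0.71; Ahsp -0.57 ± 1.59, Hbb-b1 -0.15 ± 1.498). Monocyte and dendritic markers averaged -0.04 with a median of 0.00 (0.69; Cd14 -0.43 ± 0.34, Zbtb46 0.21 ± 0.11), and neutrophil markers averaged 0.02 with a median of -0.02 and a camera direction of lower (0.98; S100a9 0.62 ± 0.66, with Cxcr2 well above background in 4 of 6 tamoxifen and 1 of 6 oil readings). In each of these 6 lists 0 members passed adjusted over the list alone. T and NK cell markers passed in 6 of 21 alternatives, B and plasma cell markers in 3 of 21, and alveolar macrophage markers in 15 of 21. The endothelial mean was 0.16 without couple 1 (adjusted p = 7.0e-04), and the erythroid mean was -0.66 without couple 2 and 0.38 without couple 3 (0.023 and 0.032).

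Signalling and metabolic lists did not pass either. ROR and Wnt5a receptors and ligands averaged 0.05 ± 0.10 (camera, adjusted p = 0.33; Ror1 0.40 ± 0.21, Celsr1 -0.42 ± 0.18), caveolae genes -0.05 ± 0.26 (0.69; Cav2 -0.30 ± 0.46, Cavin2 0.25 ± 0.43) and EGFR-MAPK response genes -0.03 ± 0.08 (0.90; Errfi1 -0.59 ± 0.31, Etv4 0.48 ± 0.23). Interferon response genes averaged 0.10 ± 0.15 (0.055; Ifit1 0.23 ± 0.14, Ifit2 0.23 ± 0.20), inflammatory cytokines 0.02 ± 0.06 with a camera direction of lower (0.90; Saa3 -1.33 ± 0.71, Cxcl5 1.09 ± 1.10) and sterol synthesis genes 0.02 ± 0.18 (0.54; Nsdhl 0.23 ± 0.10). Unfolded protein response genes averaged -0.12 ± 0.16 (0.12; Herpud1 -0.86 ± 0.22, Dnajb9 -0.40 ± 0.20) and xenobiotic metabolism genes -0.03 ± 0.18 (0.33; Cyp3a13 -0.60 ± 0.18, Por -0.32 ± 0.03). Herpud1, a factor of endoplasmic reticulum protein degradation, and Cyp3a13, a cytochrome P450, each passed adjusted over the list alone, and 0 members of the other 6 lists did. With median centring the EGFR-MAPK and xenobiotic means were above 0, at 0.0048 and 0.01. The interferon list passed in 8 of 21 alternatives, with a mean of 0.18 (camera, adjusted p = 0.037) for the scanner software's log ratio and the series table alike, and the unfolded protein response in 3 of 21. Over all alternatives the interferon adjusted p ran from 5.3e-04 to 0.84. Leaving out a couple brought some of these past the threshold: interferon at 0.18 and the unfolded protein response at -0.17 without couple 2 (camera, adjusted p = 5.3e-04 and 0.019), sterol synthesis at 0.13 without couple 1 (0.0096) and caveolae at -0.20 without couple 3 (0.032).

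**Figure D3:**
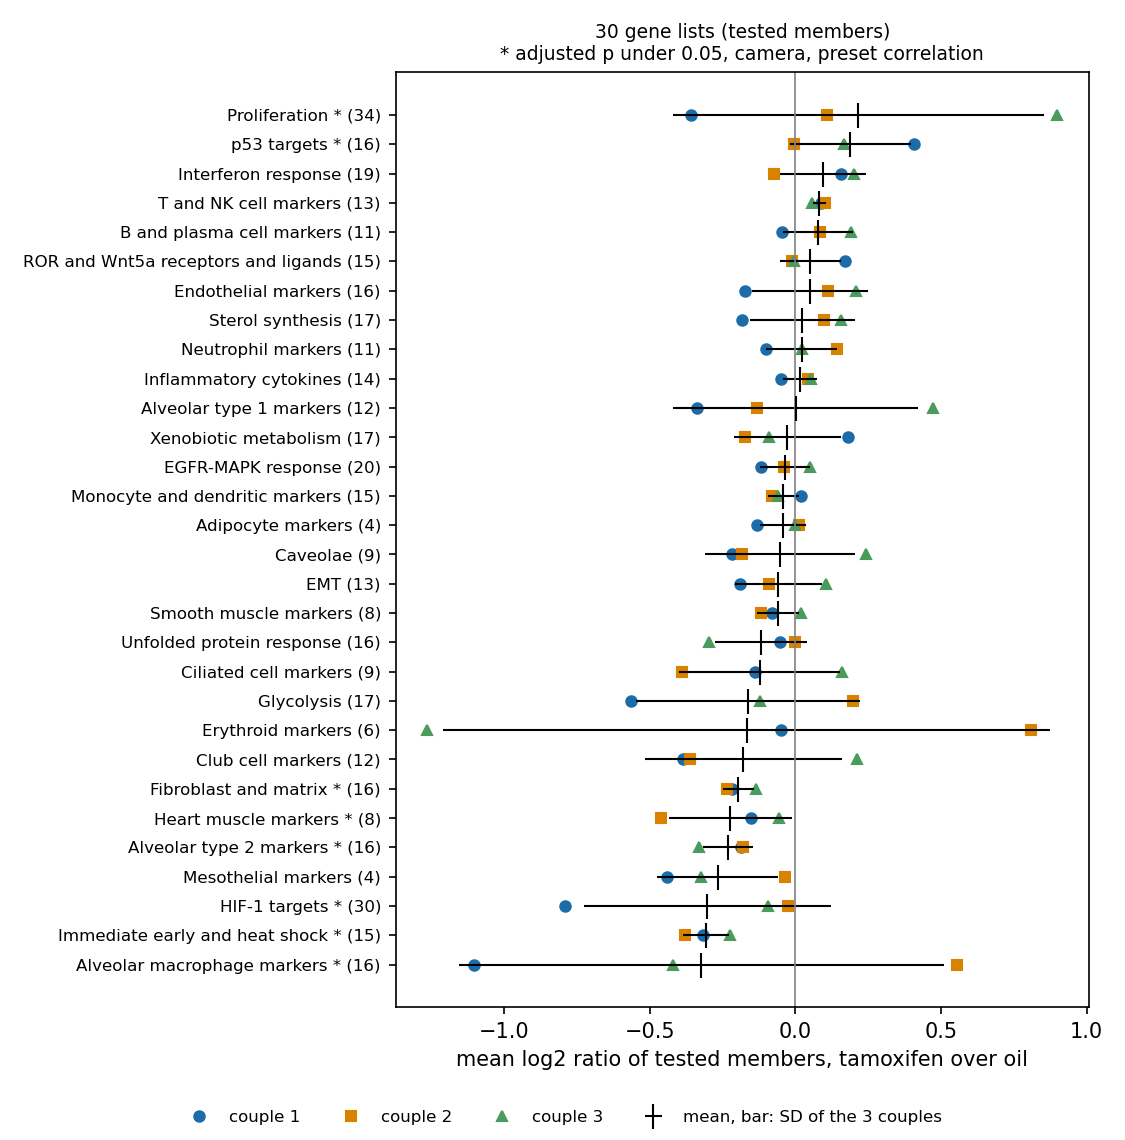
Mean log2 ratio of tamoxifen over oil (x axis) of the tested members of each of 30 gene lists, with a point per couple, a tick at the mean and a bar of 1 SD over the 3 couples, and an asterisk for lists past camera with the preset correlation. Immediate early and heat shock, alveolar type 2 and fibroblast lists have all 3 points below 0, while alveolar macrophage markers run from -1.10 to 0.55 and proliferation from -0.36 to 0.90.

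Sex-linked genes showed that the samples of couple 1 differ. In couple 1, Eif2s3y was well above background in tamoxifen on 2 of 2 arrays and in oil on 0, at least 10.3-fold brighter in tamoxifen, and other Y-linked probes were likewise brighter in tamoxifen, Uty at least 1.92-fold and Ddx3y at least 1.68-fold. Xist, the RNA that silences the second X chromosome of females, was at a log2 ratio of -2.13 in the same couple, with tamoxifen well above background on 1 of 2 arrays. In couple 2, Xist was read in both samples, at a log2 level of 9.09 in tamoxifen and 8.99 in oil, with no probe of Eif2s3y, Uty or Ddx3y well above background. In couple 3, Eif2s3y was read in both samples, at 10.7 and 10.1, and Xist in neither. The samples of couple 3 were still not equal in Y-linked signal. The brightest probes of Eif2s3y, Uty and Ddx3y had log2 ratios of 0.63, 0.79 and 0.33 there, and that of Kdm5d -0.12. Eif2s3y was thus read in tamoxifen samples 1 and 3 but, among the oil samples, only in sample 3. The groups are therefore not balanced in sex-linked signal, and every comparison of tamoxifen with oil here carries this difference, mainly through couple 1. Different Kdm5d probes disagreed: the brightest was well above background in all readings and at -0.06 over the 3 couples, while another was at least 3.41-fold brighter in tamoxifen in couple 1.

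**Figure D4:**
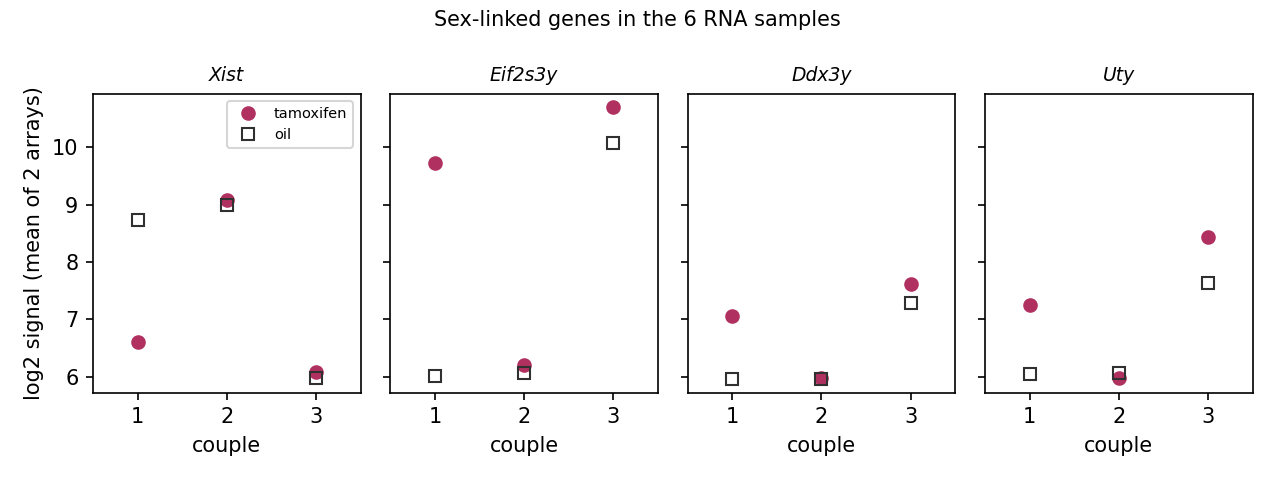
Log2 level per sample (y axis) of sex-linked probes in the tamoxifen and oil samples of the 3 couples, each the mean of 2 dye-swapped arrays. In couple 1 the tamoxifen sample has Eif2s3y signal (9.73) and the oil sample has Xist signal (8.74). In couple 2 both samples have Xist signal, and in couple 3 both have Y-linked signal, higher in tamoxifen. Kdm5d, whose probes disagree, is not drawn.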

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

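The tests of the HIF-1 targets in couple 1 and of Ror1 were chosen only after those results were seen, and the other splits of the samples were planned.

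Each gene was tested with 1 probe, and among the 36130 probes left outside the comparison 9 were well above background on both arrays of a tamoxifen sample and on neither array for the oil sample of the same couple, with a bound of 2-fold or more. In couple 1 these were probes of the Y-linked genes Kdm5d (at least 3.41-fold) and Eif2s3y (at least 2.36-fold), 2 probes of the X-linked gene Smarca1 (at least 2.305-fold and 2.295-fold) and a probe of Habp2 on chromosome 19 (at least 2.02-fold). In couple 2 they were Gm2085 (at least 3.87-fold), Dmrta2 (at least 2.27-fold) and Camkv (at least 2.09-fold), and in couple 3 Tppp (at least 2.06-fold). None of these probes met the condition in more than 1 couple. Probes well above background in oil but not in tamoxifen were not looked for. With 3 samples per group, no test for a single sample far from its group was made.

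HIF-1 targets were lower almost entirely in couple 1, where the list mean was -0.79. A bias of the dyes or of an array is argued against, since the higher of the 2 dye orientations of couple 1 still had a list mean of -0.73. The samples of couple 1 also differ in sex-linked signal. Over couples 2 and 3, where tamoxifen and oil samples had the same of Xist and Eif2s3y read, the list mean was -0.059. Sex and the other differences between the 2 samples of couple 1 cannot be told apart, because only couple 1 sets a sample with Y-linked signal against a sample without it. A lower share of alveolar macrophages could also go with it (markers at -1.10 in couple 1), but in couple 2 those markers were at 0.55 while HIF-1 targets stayed at -0.02, too few couples to decide, and an effect of Ror1 itself stays untested.

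Ror1 had a ratio above 0 in the samples labelled tamoxifen, where a deleted gene would be lower. A dye bias is argued against by the lowest of the 6 arrays, which was at 0.061 and so on the same side of 0 as the rest. More fibroblasts as the whole cause would raise the fibroblast and matrix list as far as Ror1. The list's highest couple mean was -0.13. Its means plus 2 SE over its genes were 0.010, 0.079 and 0.087 in couples 1, 2 and 3, below Ror1 at 0.58, 0.44 and 0.18. This argues against that cause only by a bar set after the values were seen. The stricter bar of 2 SE from 0, used below for clock, heat shock and p53 genes, would leave it undecided. The probe may lie outside the removed part and read RNA that recombination leaves in place: its mean of 0.40 cannot be told apart from tumors in which little of the gene was removed, as the labels do not name the floxed exon. A biological rise of the remaining transcript was not tested.

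Other splits of the samples were run for the counts of genes and lists. Turning the signs of the 3 couples makes 4 splits, too few for a share under 0.05: 1 of 4 had at least the 1435 genes at an unadjusted p under 0.05 of the real split, and the highest other had 1129. For gene lists past camera, 2 of 4 had at least the 8 of the real split, and the highest other had 11. With the channels taken apart, the 10 splits of 3 against 3 samples are likewise too few for a share under 0.05: 4 of 10 had at least the 1 gene of the real split with a highest other of 5, and 7 of 10 had at least its 7 lists with a highest other of 14. The split with 5 genes and 14 lists set the tamoxifen samples 1 and 3 and oil sample 3 against the rest, which parts the samples by Y-linked signal and so points to a structure of the samples. Its genes, named after their values were seen, were Eif2s3y, Xist, another probe under the name XIST, Gm33272 and a transcript without a gene name. Differences are not given for them, since Eif2s3y and Xist were at background in some of the samples set against each other.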

How the results depend on the processing

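None of the tests here was chosen after a result was seen. No gene passed in 19 of 22 alternatives for the count of changed genes. It was 9 with the 6 arrays and the couple as a random block, where dye swaps correlated at 0.89, and 179 with the 6 arrays as if independent, which treats dye swaps as replicates. Among the 20 genes named by rule for a small p in their direction, 0 of 400 values under the alternatives changed sign. These genes were picked for having 1 direction on all 6 arrays, so alternatives that only drop or reweight those arrays could not turn it. Ror1 stayed above 0 and short of the threshold in 21 of 21, from 0.31 to 0.51. HIF-1 targets kept their side of the threshold in 19 of 21: with an estimated correlation the mean of -0.30 no longer passed (adjusted p = 0.84), and leaving out couples gave -0.44 to -0.059, with the call lost without couple 1. Only the alternative with an estimated correlation changed the preset correlation, so list counts out of 21 hardly test that setting. The count of lists past camera, 8, was 13 with the scanner software's log ratio, 13 with the series table (the same 8 were among the 13 in both), 0 with an estimated correlation, and 6 to 12 with a couple left out. Of the same 8, only 4 passed without couple 1, 7 without couple 2 and 4 without couple 3. Of 609 values of the other lists, 519 kept direction and side of the threshold, 41 passed newly, 23 no longer passed and 26 changed sign. Of 1912 values of named genes these were 1860, 40, 0 and 12. A value that changed sign is counted only as such, though some list values that did so also crossed the threshold. The cause of these moves was not tested. Estimating the correlation raises a list's error where its members move together, but it also leaves camera few degrees of freedom. Heart muscle markers had an estimated correlation of -0.065. Their unadjusted p still went from 0.011 with the preset to 0.12 with the estimated correlation (camera). Signal over background limits dim genes: 15 tested genes were not well above background in any tamoxifen reading and 10 in any oil reading, and a doubling of the tamoxifen channel was read as a log2 ratio of 0.66 in the dimmer genes. Without the filter on dim probes 2571 genes had an unadjusted p under 0.05, and with only probes above background on all readings 1297, and 0 passed in both.

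Pairing was looked at apart from the arrays. With the channels taken apart, deviations of same-numbered samples from their group means correlated across genes at 0.095, 0.16 and 0.16, and other pairs at -0.20 to 0.088. Each sample thus correlated best with its own number, a hint from the data only, since same-numbered samples also share arrays. With no replicate block 1 gene passed, Cox6a2, and with the replicate block 0, and for lists 7 and 8.

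Some values changed sign with the processing. Nkx2-1 (main value -0.03) was at 0.014 with the scanner software's log ratio, 0.014 with the series table, 0.027 with median centring, 0.010 with the mean of a gene's probes and 0.057 with tamoxifen in Cy5 only. Ms4a1, at 0.15 and above 0 on 6 of 6 arrays with its brightest probe, was at -0.082 with the mean of its probes, and Retn at 0.049 with tamoxifen in Cy5 only. Median centring put EGFR-MAPK response at 0.0048, xenobiotic metabolism at 0.011 and monocyte and dendritic markers at 0.0017. With tamoxifen in Cy5 only, sterol synthesis was at -0.0012. With tamoxifen in Cy3 only, inflammatory cytokines were at -0.029 and alveolar type 1 markers at -0.017, and with array weights the latter were at -0.0097.

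Leaving out each couple in turn gave ranges that crossed 0. Omitting couple 1 changed the sign of glycolysis (-0.34 to 0.039), ROR and Wnt5a receptors and ligands (-0.0080 to 0.084), EGFR-MAPK response (-0.078 to 0.0066), EMT (-0.14 to 0.0074), alveolar macrophage markers (-0.76 to 0.067) and adipocyte markers (-0.068 to 0.0044). Omitting couple 2 changed that of Ror2 (-0.24 to 0.017), ciliated cell markers (-0.26 to 0.011) and neutrophil markers (-0.038 to 0.084). Omitting couple 3 changed that of Ahsp (-1.48 to 0.012), Hbb-b1 (-0.79 to 0.68), proliferation (-0.12 to 0.50), inflammatory cytokines (-0.0031 to 0.049), alveolar type 1 markers (-0.23 to 0.17), endothelial markers (-0.031 to 0.16) and erythroid markers (-0.66 to 0.38). More than 1 omission did so for Nkx2-1 (-0.13 to 0.031; couples 2 and 3), caveolae (-0.20 to 0.031; couples 1 and 2), sterol synthesis (-0.042 to 0.13; couples 2 and 3) and xenobiotic metabolism (-0.13 to 0.045; couples 2 and 3).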

Other observations

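The clock and glucocorticoid gene lists and their tests, and Cd36, Cox7a1 and Wnt5a, were chosen only after the data were seen, while the tests on further heat shock factor and p53 targets were written before their values were looked at. For all of them the bar of 2 SE of a list's members in each couple was set after the values were seen.

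Genes driven by the circadian clock were looked at as a group. All 8 tested clock output genes had a ratio below 0, with couple means of -0.42, -1.14 and -0.28 and a list mean of -0.61 ± 0.46 (SD, n = 3 couples): Dbp was at -1.34, Per1 at -0.91, Tef at -0.61, Per3 at -0.50, Ciart at -0.48, Per2 at -0.44, Nr1d2 at -0.35 and Nr1d1 at -0.29. No p is given for this list or the next, as both were picked with the values in view and Per1 was already among the lower genes with the smallest p. Per2 at 0.15 in couple 1 and Nr1d2 at 0.08 in couple 3 were above 0. Genes that glucocorticoids induce had couple means of -0.89, -0.16 and -0.30, with Mt2 at -1.16, Zbtb16 at -0.69, Klf9 at -0.30, Sgk1 at -0.28, Fkbp5 at -0.21 and Tsc22d3 at -0.07. Of these 6, only Zbtb16 and Klf9 kept the sign in all 3 couples: Mt2, Sgk1 and Fkbp5 were at 0.13, 0.45 and 0.09 in couple 2, and Tsc22d3 was at 0.27 and 0.09 in couples 1 and 3. Cd36, a fatty acid receptor, was at -0.68 ± 0.14 (limma, adjusted p = 0.67; lower on 6 of 6 arrays). Cox7a1, another muscle form of a cytochrome c oxidase subunit, was at -0.0023 where Cox6a2 was at -1.86, and Wnt5a, the ligand of Ror1, was at 1.10, 0.30 and -0.33 in couples 1, 2 and 3.

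Clock output ratios below 0 could come from another hour of tumor collection in the 2 treatments. Genes of the opposite phase would then be higher, and they had couple means of -0.16, 0.32 and -0.19, with a lowest of -0.19 over 4 tested genes that went both ways. In couple 2, where clock output was lowest, Arntl, Nfil3, Clock and Cry1 were at 0.62, 0.29, 0.25 and 0.13. In couples 1 and 3 Nfil3 was at -0.63 and -0.85 and Clock at -0.06 and -0.03, while Arntl and Cry1 were above 0. The hour of collection cannot be told apart from other causes with these genes. A lower glucocorticoid response stays open as well: the highest couple mean of the glucocorticoid-induced genes was -0.16, in couple 2, where the clock output genes were lowest and 3 of the 6 genes were above 0. An effect of Ror1 or of tamoxifen itself stays open, as untested.

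A hypothesis for the low immediate early and heat shock genes was less heat or handling stress before RNA isolation in the tamoxifen samples. Other heat shock factor targets would then be lower too, but their couple means were 0.06, 0.09 and -0.09, the highest at 0.090, which leaves it undecided. For p53 targets the hypothesis was p53 activity after Cre recombinase, which can damage DNA. Of 14 other p53 targets 7 were higher and 7 lower, with a mean of 0.05 and a lowest couple mean of -0.039, which leaves that undecided as well.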
